A study of Mus musculus with 6 samples.

How the data were processed

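Per the labels, hepatocytes of 3 mice were sorted into TERT(High) and TERT(Low) cells, RNA was purified with an RNeasy micro kit and libraries were made with the KAPA stranded mRNA kit. Per the submitters' processing notes, Trim Galore 0.4.0, TopHat2 2.0.13, DESeq2 (version not given) and the genome mm10 were used, and the tool that counted reads, its strand setting and its gene annotation are not given in the sources used here. Reads of overlapping genes, antisense transcripts and close paralogs are therefore uncertain, most of all for the major urinary proteins. The deposited count table holds raw counts per gene and library, per the file headers named by Entrez gene number and symbol, with no scaling applied by the authors. In the authors' deposited table of results the signal value of each gene is its baseMean, the mean over libraries of counts divided by size factors, as DESeq2 names this column. The authors' log2 fold changes and their standard errors compare TERT(High) with TERT(Low), a direction read from the counts. The authors' p-value columns hold the p and the adjusted p of their own DESeq2 comparison. All 6 libraries were used, and the count table holds 15565 genes, each with at least 6 counts in some library. Mitochondrially encoded genes are not in the count table, so that list was not analysed here, and neither was Krt19.

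Before the data were examined the main test, the 25 alternatives, the 58 gene lists and the rule for naming genes were fixed. The main test was edgeR 4.0.16 in R 4.3.3, with filterByExpr by group, TMM scaling, robust quasi-likelihood fits and Benjamini-Hochberg adjusted p under 0.05, and the common biological coefficient of variation was 40.7%. The standard error is the absolute log2 fold change divided by the square root of F, and is left empty for genes with next to no change, where it is not defined. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with the correlation estimated from the libraries and with fry as alternatives. Alternatives further changed the scaling, the filter, the tool (DESeq2 1.42.0, limma-voom with sample weights), the threshold and the libraries. Named are Tert, the 10 largest increases and decreases among genes past the threshold with the same sign in all mice and at least 5 CPM in the higher group, leaving out unnamed gene models, the 5 most abundant such genes in each direction, up to 4 members of each list with the largest change past the threshold (or its 2 most abundant members), and a fixed set of liver landmark genes. Not every gene this rule names is reported here. The labels state that both populations of a pair came from the same mouse. The main test fitted the group alone, so its p-values treat the libraries as independent and ignore this pairing. As a check, the deviations of a mouse's 2 libraries from their group means had correlations of -0.089, 0.733 and 0.601 for mice 1, 2 and 3. A block for the mouse was an alternative and lowered the coefficient of variation to 29.64%.

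edgeR and DESeq2 were tried on 6 simulated data sets built from these libraries, with 200 changed genes each. edgeR recovered 0.26% of genes changed 1.5-fold, 4.15% of those changed 2-fold and 61.6% of those changed 4-fold, with 25 false calls among 281. DESeq2 recovered 4.23%, 27.4% and 74.2%, with 281 false calls among 702 (40.0%), a larger share than edgeR in these simulations. Only 200 of 13288 genes changed in each simulation, and mice did not differ. The share of false calls depends on how many genes change, so these shares do not carry over to the real comparison. The list with a built-in change was called, and 0 of 20 unchanged lists were. Genes were drawn independently there, so the simulation cannot show how the list test behaves when members are correlated. The correlation estimated from the libraries was 0.411 for cytosolic ribosomal proteins.

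Coordinates and gene matches are from the RefSeq annotation of GRCm38.p6, which matched 99.7% of genes by Entrez number. Transcript lengths are from GENCODE M21 for 93.1% of genes. Further tools were GenomicRanges 1.54.1, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

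Several choices followed the results. The length analysis and 5 alternatives (the length and GC correction alone, with the mouse as a block and with DESeq2, edgeR without robust dispersion, and DESeq2 with each library left out) were added after the main result was seen. Length was first the median over the coding transcripts of a gene. It was replaced by the transcript with the longest coding sequence because the median gave implausibly short values for long genes. That change raised the correlation with the log2 fold change and reduced what the correction left of the ribosomal protein and complex I differences. The chosen transcript was long for some genes of short coding sequence, such as Ndufb2 (4371 nt, coding 315 nt) and Atp5g1 (4715 nt, coding 408 nt). For these 2 genes the correction enlarged the decrease, from -0.93 to -1.26 and from -0.78 to -1.07, whereas the median decrease of called lower genes shrank. A first test at gene level asked what share of the change called genes kept, and was dropped because it could not fail. A test on a held-out mouse replaced it. Its first run without an expression minimum gave differences of 0 for the lower genes, after which the minimum of 5 CPM was set and the directions were separated. The rule for length-matched lists was changed after its values were seen to need both transcript and coding length. The rule for endothelial RNA was also tightened after its values were seen, and the earlier rule would have been met. Sign changes of genes or lists past no threshold in either fit were counted as unchanged.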

Results

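Hepatocytes, the parenchymal cells of the liver, were isolated by collagenase perfusion from 3 C57BL/6 mice aged 2 months and sorted into TERT(High) and TERT(Low) cells, and polyadenylated RNA of each sorted population was sequenced. Both populations came from each mouse, which gave 6 libraries in 2 groups of 3. Tert encodes the catalytic subunit of telomerase, the enzyme that extends chromosome ends. By genotype the mice carried CreERT2, a tamoxifen-inducible recombinase, at 1 copy of Tert and a Cre-dependent Tomato reporter at 1 copy of the R26 locus. The design asks which genes differ in RNA level between hepatocytes of high and of low Tert expression within the same livers. Library totals in units of 1e6 counts were 54.1, 64.1 and 53.6 for TERT(High) cells of mice 1, 2 and 3, and 76.2, 56.0 and 55.4 for TERT(Low) cells. The count table held 15565 genes, of which 13288 passed the expression filter and were tested. Levels are counts per 1e6 counts scaled by TMM (CPM), as mean ± SD over the 3 libraries of a group, and differences are TERT(High) over TERT(Low) with the standard error (SE) of the log2 fold change. Coordinates are on mm10 (GRCm38).

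Tert itself (Entrez gene 21752, chromosome 13, 73626911 to 73649843) was close to the limit of detection in every library. It had 38, 33 and 30 counts in TERT(High) cells of mice 1, 2 and 3 and 21, 21 and 12 counts in the TERT(Low) cells of the same mice. The level was 0.560 ± 0.0543 CPM (SD, n = 3) against 0.305 ± 0.0882 CPM, a ratio of 1.84, and was higher in TERT(High) cells of all 3 mice. An exact two-sided permutation test gave p = 0.1, the smallest value that 3 against 3 freely exchanged libraries allow. That permutation test treats the libraries as independent and ignores the pairing by mouse. In edgeR's test across all genes the log2 fold change of 0.87 (SE 0.44) had an adjusted p of 0.249. Terc, the RNA template of telomerase, had 0 to 1 counts in TERT(High) libraries and 2 to 7 counts in TERT(Low) libraries, below the expression filter. Such counts in libraries of polyadenylated RNA measure neither the level of Terc nor the direction of a difference.

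**Figure D1:**
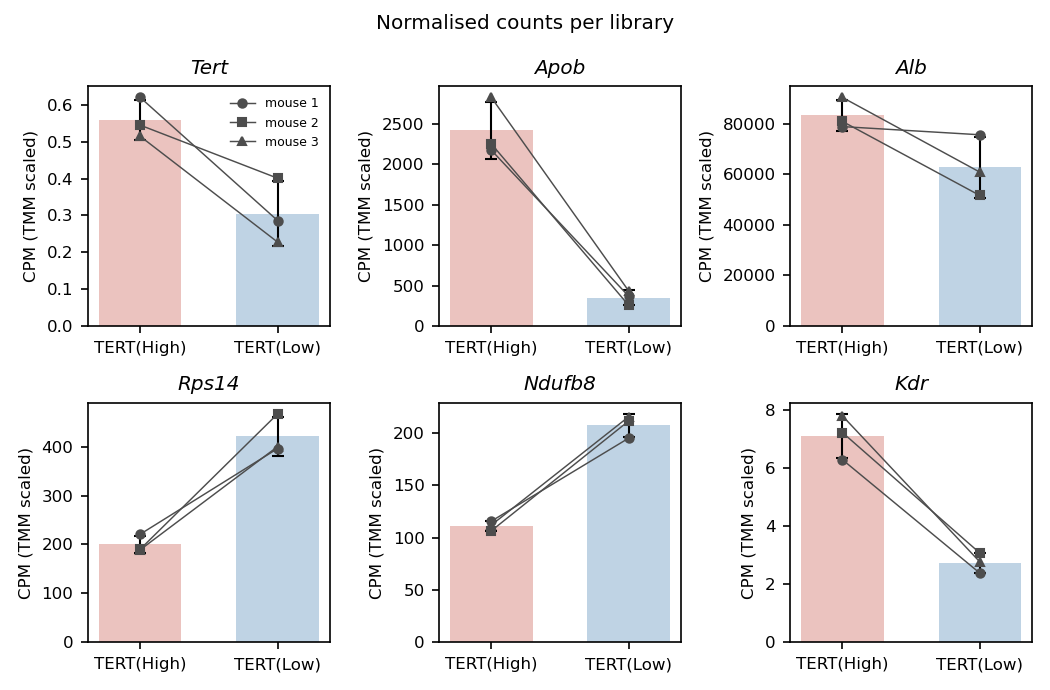
TMM-scaled CPM (vertical axis, from 0) of Tert, Apob, Alb, Rps14, Ndufb8 and Kdr in TERT(High) and TERT(Low) hepatocytes. Bars are means and error bars SD over 3 libraries, markers joined by a line are the 2 libraries of 1 mouse, and Apob lies at 2421 ± 357 CPM in TERT(High) and 352 ± 90.3 CPM in TERT(Low) cells.

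TERT(High) hepatocytes held more RNA of Apob, the structural protein of very-low-density lipoproteins, and of several chromatin regulators. They held less RNA of many proteins of the ribosome, the respiratory chain and the ATP synthase, lists that passed camera at its preset correlation and not with an estimated one (adjusted p from 0.453 to 0.553). Apob (Entrez gene 238055, chromosome 12, 7977629 to 8016839) reached 2421 ± 357 CPM in TERT(High) and 352 ± 90.3 CPM in TERT(Low) cells, a 6.88-fold difference (log2 fold change 2.78, SE 0.25, adjusted p = 0.0241). Its transcript has 13934 nt, and after the length and GC correction described below the log2 fold change was 1.99 (SE 0.20, edgeR adjusted p = 0.0617). The median fold among called genes was 2.44 for the genes that were higher (median SE of the log2 fold change 0.22) and 1.70 for those lower (median SE 0.14), so the test asked for larger folds among the higher genes. For genes picked in 2 mice, the median log2 differences of higher and lower genes in the held-out mouse were 0.56 and -0.59 in mouse 1, 1.16 and -0.81 in mouse 2, and 1.31 and -0.75 in mouse 3. Of the genes higher in TERT(High) cells 468 differed by over 2-fold, and of the genes lower 12 did.

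By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 588 of the 13288 genes were higher and 493 lower in TERT(High) cells, 8.14% in all, with adjusted p from 0.0241 to 0.04996. All 1081 genes had the same sign in the 3 mice. At an unadjusted p under 0.05, 2164 genes were higher and 1649 lower. The 3 TERT(High) values lay wholly above the 3 TERT(Low) values for 2322 genes and wholly below for 2115, together 33.4% of genes, where chance gives 10% if libraries are freely exchangeable, which pairs from the same mouse are not. The balance of directions followed the scaling: higher genes made up 54.4% of calls with TMM, 43.2% with upper-quartile scaling (542 higher, 712 lower) and 97.1% with library totals alone (628 higher, 19 lower), under which the median log2 fold change of all genes was 0.14 in place of -0.01. All adjusted p lay close to the threshold, and edgeR called 0 genes when any library except TERT(High) of mouse 1 was left out (libraries TERT(High) 2 and 3, TERT(Low) 1, 2 and 3), and 0 when mouse 1, 2 or 3 was left out, with 1071 to 1958 genes higher and 748 to 1515 lower at an unadjusted p under 0.05. Without TERT(High) of mouse 1 it called 937 higher and 713 lower, and DESeq2 called 772 to 1662 higher and 763 to 1584 lower with each library left out in turn, including 558 to 586 of the 588 and 489 to 493 of the 493.

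The 10 largest increases were taken among genes of at least 5 CPM. Mia2 (chromosome 12, 59095582 to 59190220) and Mia3 (chromosome 1, 183326236 to 183369565), which load bulky cargo into vesicles at the exit sites of the endoplasmic reticulum, were higher by 2.73 (SE 0.22) and 2.57 (SE 0.31) on the log2 scale, with adjusted p of 0.0241 and 0.0274. Mia3 went from 7.50 ± 1.38 CPM in TERT(Low) to 44.5 ± 15.5 CPM in TERT(High) cells. Golga3, a golgin of the Golgi apparatus (chromosome 5, 110176857 to 110226470), had a log2 fold change of 2.42 (SE 0.44, adjusted p = 0.0322). Its edgeR adjusted p was 0.0505 in the fit with the mouse as a block. Nbeal1 (chromosome 1, 60178740 to 60338328) showed the largest increase, 2.93 (SE 0.46), from 0.693 ± 0.295 to 5.29 ± 2.24 CPM. Hspg2, the basement membrane proteoglycan perlecan (chromosome 4, 137468751 to 137570630), differed by 2.69 (SE 0.60), and Gvin1, an interferon-inducible GTPase of a family of near-identical copies whose reads are uncertain (chromosome 7, 106156535 to 106215340), by 2.68 (SE 0.24). Vps13a, a lipid transfer protein (chromosome 19, 16615366 to 16781071), Ranbp2, a nuclear pore component (chromosome 10, 58446852 to 58494155), and Cep350, a centrosomal protein (chromosome 1, 155844964 to 155973270), had log2 fold changes of 2.63, 2.52 and 2.36 with SE of 0.59, 0.37 and 0.42. Among the most abundant genes that were higher was also Hc, which encodes complement C5, at 552 ± 133 against 176 ± 29.1 CPM. Hspa9, the mitochondrial Hsp70, and Eif4g2, a translation initiation factor, followed with log2 fold changes of 0.64 (SE 0.15) and 0.61 (SE 0.13). Hspa9 and Eif4g2 had adjusted p of 0.0642 and 0.0529 with DESeq2 size factors, neither passed with upper quartiles, and Eif4g2 had a log2 fold change of -0.04 after the length and GC correction.

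The 10 largest decreases were smaller, at most 1.20 on the log2 scale. Zap70, a kinase of T cell receptor signalling (chromosome 1, 36761798 to 36782821), fell by 1.20 (SE 0.25, adjusted p = 0.0395), and Metrn, which encodes the secreted factor meteorin (chromosome 17, 25794571 to 25797045), by 1.13 (SE 0.17, adjusted p = 0.0277). Tm7sf2, a sterol reductase of cholesterol synthesis (chromosome 19, 6062821 to 6067850), went from 414 ± 71.1 CPM in TERT(Low) to 193 ± 43.0 CPM in TERT(High) cells. The ribosomal protein genes Rps14 (chromosome 18, 60774596 to 60778546) and Rplp1 (chromosome 9, 61913283 to 61914510) had log2 fold changes of -1.07 (SE 0.15) and -1.01 (SE 0.14). The mitochondrial assembly factors Ndufaf8 (chromosome 11, 120098934 to 120100424) and Fmc1 (chromosome 6, 38534861 to 38539449) were at 10.7 ± 0.429 against 21.5 ± 4.01 CPM and 16.0 ± 0.154 against 31.9 ± 1.94 CPM. In the authors' deposited table of results the log2 fold change of Ndufaf8 was -0.21, with an adjusted p of 0.663. Tmem160 (chromosome 7, 16452779 to 16455496), Apoc4 (chromosome 7, 19678084 to 19681460) and Tmem219 (chromosome 7, 126886219 to 126928821) were at 17.0 ± 4.45 against 36.3 ± 4.54, 694 ± 33.6 against 1396 ± 182, and 18.8 ± 3.09 against 37.6 ± 0.540 CPM. Among the most abundant genes that were lower, Apoa2, an apolipoprotein of high-density lipoproteins, was at 3991 ± 398 against 6727 ± 771 CPM and Sod1, the cytosolic superoxide dismutase, at 706 ± 13.2 against 1215.5 ± 36.9 CPM. Cyb5a, the electron carrier cytochrome b5, was at 1208 ± 80.5 against 1979 ± 264 CPM, and Rps2 at 638 ± 8.54 against 1130 ± 162 CPM.

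**Figure D2:**
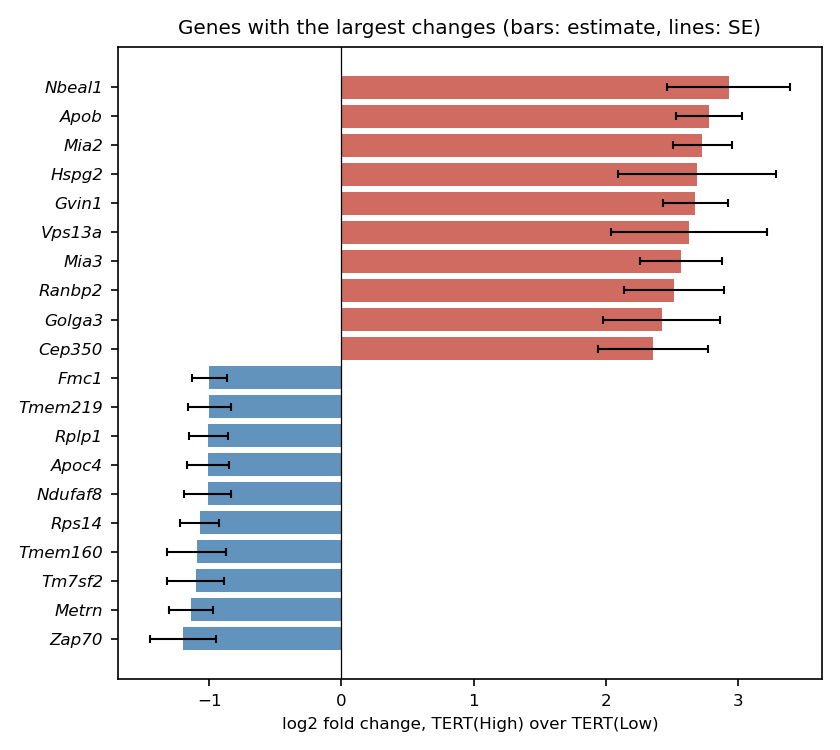
Log2 fold change of TERT(High) over TERT(Low) (horizontal axis) for the 10 largest increases and the 10 largest decreases among genes past the threshold, with bars of 1 SE (n = 3 libraries per group). Increases reach 2.93 for Nbeal1 and decreases -1.20 for Zap70.

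Genes with long transcripts were mostly higher and genes with short transcripts mostly lower. Many genes named above and many gene groups described next follow this relation. Among those that do not are neutrophil and macrophage markers, with median transcripts of 1222 and 1382.5 nt and median log2 fold changes of 2.12 and 0.79. Across the 12548 tested genes with an annotated coding transcript, the log2 fold change had a Spearman correlation of 0.482 with transcript length and 0.515 with coding length (genes are not independent replicates). In the shortest length quintile 1 gene was higher and 373 were lower, with a median log2 fold change of -0.46. In the longest quintile 381 were higher and 4 lower, with a median of 0.65. The median transcript was 5849 nt for called genes that were higher, 1045 nt for those lower and 2962.5 nt for all tested genes. Slopes of log2 counts on log2 transcript length, each relative to the mean of the 6 libraries, were 0.0847, 0.139 and 0.2801 in the TERT(High) libraries of mice 1, 2 and 3 and -0.0413, -0.268 and -0.194 in the TERT(Low) libraries. After removal of each library's trend with transcript length and GC content, a setting added after the data were seen, edgeR called 0 genes, with 1636 higher and 675 lower at an unadjusted p under 0.05 and a smallest adjusted p of 0.0617. The same correction gave 452 higher and 113 lower genes with the mouse as a block, and 740 and 317 with DESeq2. The median log2 fold change of the called genes went from 1.29 to 0.87 (median SE 0.22 before and after) for the higher and from -0.77 (median SE 0.14) to -0.28 (median SE 0.16) for the lower genes, and 1043 of the 1081 kept their sign.

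**Figure D3:**
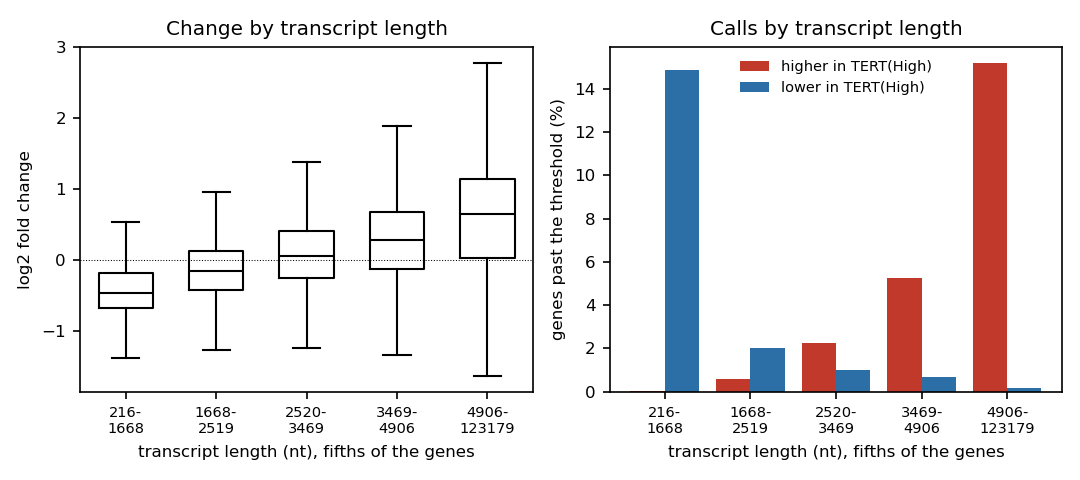
Left, box plots of the log2 fold change of TERT(High) over TERT(Low) for tested genes in quintiles of transcript length (nt), without outliers. Right, bars of the percent of genes in each quintile past the threshold, separately for genes higher and lower in TERT(High) cells. The median moves from -0.46 in the shortest to 0.65 in the longest quintile of length.

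Of 58 gene lists fixed before the data were examined, 57 had at least 3 tested members. By camera with a preset correlation of 0.01, 4 lists were higher and 9 lower in TERT(High) cells at an adjusted p under 0.05. With a correlation estimated from the libraries 0 lists passed. The rotation test fry, which asks whether members move on balance 1 way, passed 7 lists, all lower.

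Genes of the ribosome and of oxidative phosphorylation were lower together. Of 82 cytosolic ribosomal protein genes 58 were lower and 0 higher, 75 were lower with p adjusted over the list alone, and 80 were lower in all 3 mice (median log2 fold change -0.74, camera adjusted p = 3.15e-34). With an estimated correlation the adjusted p was 0.553, the highest of 21 alternatives, of which the lowest gave 2.91e-39. Rpl27 and Rps27 had log2 fold changes of -0.96 (SE 0.17) and -0.90 (SE 0.13). Of 78 mitochondrial ribosomal protein genes 19 were lower, and 49 with p adjusted over the list alone, among them Mrpl20 at -0.94 (SE 0.12) and Mrpl53 at -0.88 (SE 0.15). Their median was -0.49 (camera adjusted p = 4.29e-17, and adjusted p = 0.453 with an estimated correlation). Complex I of the respiratory chain, the NADH dehydrogenase, had 24 of 36 subunits lower and 34 with p adjusted over the list alone (median -0.68, camera adjusted p = 5.29e-19). Ndufb8 fell by 0.90 (SE 0.13), from 207 ± 10.8 to 111 ± 4.63 CPM. Complexes II to IV had 15 of 25 subunits lower and 20 with p adjusted over the list alone (median -0.68, camera adjusted p = 7.4e-12), including Uqcrh and Sdhc at -0.86 (SE 0.14) and -0.82 (SE 0.17). The ATP synthase had 8 of 17 lower and 15 with p adjusted over the list alone (median -0.66, camera adjusted p = 1.64e-08). The adjusted p was 0.553 with an estimated correlation for each of these 3 lists, the highest of their 21 alternatives. After the length and GC correction the medians were -0.17 for cytosolic ribosomal proteins and complex I, -0.14 for complexes II to IV, -0.09 for the ATP synthase and -0.11 for mitochondrial ribosomal proteins, with camera adjusted p of 1.21e-06, 1.32e-04, 0.00942, 0.0338 and 3.59e-07. These corrected medians depend on the transcript chosen for each gene, which for some members, such as Ndufb2, was long for its coding sequence.

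The proteasome and 3 liver-specific lists made up the rest of the lower lists. Of 31 proteasome genes 10 were lower, 13 with p adjusted over the list alone, led by the catalytic-core subunits Psmb3 and Psmb6 at -0.94 (SE 0.13) and -0.89 (SE 0.14). The list median was -0.35 (camera adjusted p = 4.89e-06, and 0.775 with an estimated correlation), and -0.02 with an adjusted p of 0.118 after the length and GC correction. Major urinary protein genes, pheromone carriers of which paralogs share reads and are uncertain one by one, had a median of -0.44 (camera adjusted p = 0.00122, and adjusted p = 0.878 with an estimated correlation). By edgeR 0 of their 21 members passed, over all genes or adjusted over the list alone, 8 were lower at an unadjusted p under 0.05, and DESeq2 and limma-voom each called 4 lower. Without mouse 3 the list missed the threshold (adjusted p = 0.214), and after the length and GC correction its adjusted p was 0.0873. Enzymes of xenobiotic conjugation had 2 of 35 members lower, Gstt2 at -0.95 (SE 0.22) and Gstt1 at -0.70 (SE 0.13), and 1 with p adjusted over the list alone (median -0.34, camera adjusted p = 0.006, and adjusted p = 0.733 with an estimated correlation). With the strict filter the adjusted p of that list was 0.0703. Of 24 cholesterol synthesis genes Tm7sf2 alone was lower, also with p adjusted over the list alone, and the list median was -0.40 (camera adjusted p = 0.0457, and adjusted p = 0.994 with an estimated correlation). The cholesterol synthesis list had an adjusted p of 0.058 with the mouse as a block, 0.142 with the strict filter, 0.294 with limma-voom, 0.152 without TERT(High) of mouse 2, 0.834 without TERT(Low) of mouse 2 and 0.821 without mouse 2, where the median was 0.02.

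Chromatin regulators formed the higher list with the smallest p. Of 34 tested members 9 were higher, and 23 higher and 1 lower with p adjusted over the list alone (median log2 fold change 1.36, camera adjusted p = 7.44e-12, and adjusted p = 0.565 with an estimated correlation). Chd1, a nucleosome remodeller, was at 9.11 ± 1.35 against 1.82 ± 0.233 CPM (2.32, SE 0.20). Setd2, the methyltransferase of histone H3 lysine 36, Ep300, a histone acetyltransferase, and Ash1l had log2 fold changes of 2.21 (SE 0.35), 1.99 (SE 0.38) and 1.94 (SE 0.27). After the length and GC correction the list median was 0.75 (camera adjusted p = 4.26e-09). Ribosome biogenesis factors went both ways, with 9 of 50 higher and 1 lower, and 16 higher and 6 lower with p adjusted over the list alone (median 0.27, camera adjusted p = 0.0125, and adjusted p = 0.708 with an estimated correlation), and the adjusted p was 0.0534 with limma-voom. Ncl, the nucleolar protein nucleolin, was 4.21-fold higher at 53.6 ± 13.3 against 12.7 ± 1.17 CPM, and Nolc1 and Bms1 had log2 fold changes of 1.68 (SE 0.36) and 1.65 (SE 0.25). With the mouse as a block the adjusted p of Nolc1 was 0.0578.

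Of the marker lists of other liver cells, those of endothelium and of neutrophils passed camera at its preset correlation. Of 28 markers of sinusoidal and vascular endothelium 7 were higher, and 11 with p adjusted over the list alone (median 0.96, camera adjusted p = 1.16e-04, and adjusted p = 0.802 with an estimated correlation). All stood at low levels: Ptprb at 6.36 ± 2.43 against 1.33 ± 0.311 CPM, Mrc1 at 5.53 ± 2.13 against 1.57 ± 0.0908 CPM, Flt4 at 5.48 ± 1.95 against 1.56 ± 0.610 CPM, and Lyve1 at 2.72 ± 0.895 against 0.988 ± 0.124 CPM. Flt4 missed the threshold with the mouse as a block (adjusted p = 0.0668). Clec4g, an abundant lectin of the same cells, was at 8.75 ± 2.08 against 9.25 ± 0.931 CPM. Of 7 tested neutrophil markers 0 passed over all genes by edgeR and 1 with p adjusted over the list alone, while 4 were higher and 1 lower at an unadjusted p under 0.05, and DESeq2 called 2 and limma-voom 1 higher. The neutrophil list had a median of 2.12 (camera adjusted p = 0.0457, and adjusted p = 0.878 with an estimated correlation). Its adjusted p was 0.108 with the mouse as a block, 0.17 with limma-voom, 0.0951 with library totals, 0.26 without TERT(High) of mouse 1, 0.136 without TERT(Low) of mouse 1 and 0.676 without mouse 1. S100a9 was at 1.57 ± 0.741 against 0.362 ± 0.226 CPM and Cxcr2 at 3.25 ± 0.915 against 6.72 ± 3.21 CPM. Markers of macrophages and Kupffer cells (median 0.79, adjusted p = 0.495), stellate cells and fibroblasts (0.31, 0.919), lymphocytes (0.19, 0.905), cholangiocytes and progenitors (-0.07, 0.91), and erythroid cells and platelets (1.09, 0.951) did not pass. Only 4 of 28 lymphocyte, 14 of 29 cholangiocyte and 7 of 14 erythroid markers were tested. These lists cannot show that the content of such cells was equal. Macrophage markers passed without TERT(High) of mouse 2 (median 1.06, adjusted p = 0.0407) and without TERT(Low) of mouse 3 (median 1.49, adjusted p = 0.0463). The erythroid list passed as lower without TERT(High) of mouse 1 (median -2.14, adjusted p = 6.04e-04) and without mouse 1 (median -2.19, adjusted p = 8.82e-04), a library in which Hba-a1, a haemoglobin chain, had 3959 counts against 118 to 802 in the other 5.

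**Figure D4:**
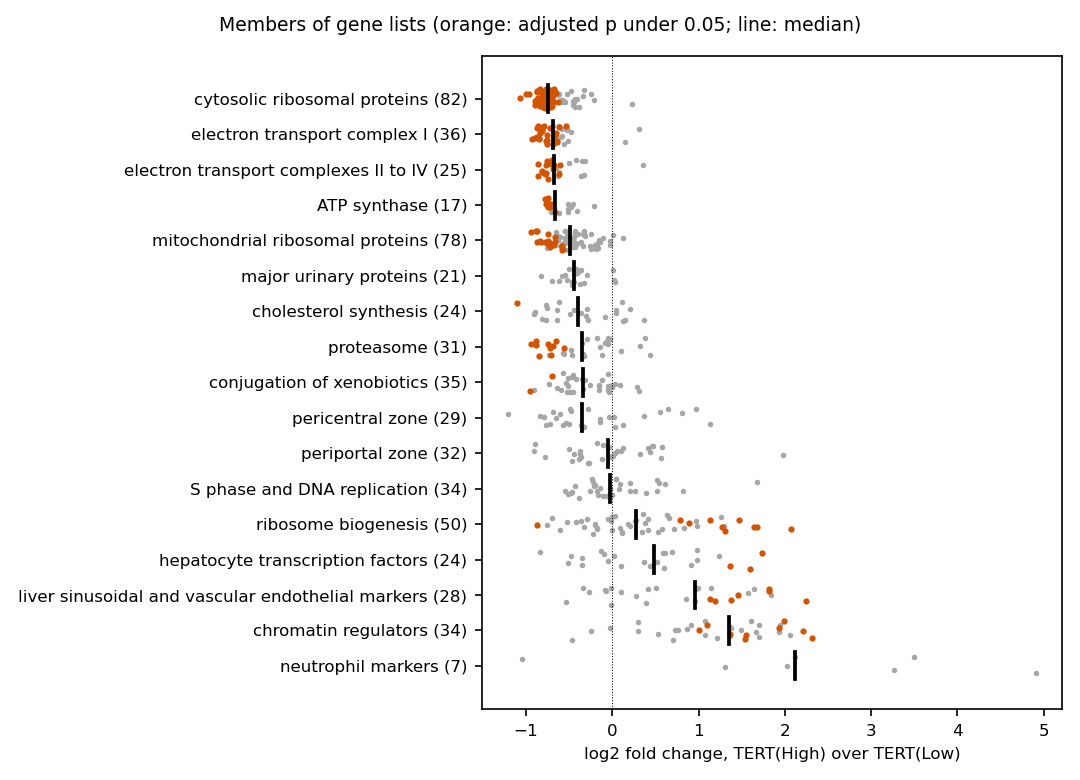
Log2 fold change of TERT(High) over TERT(Low) (horizontal axis) for each tested member of 17 gene lists, with the number of members in brackets, members past the threshold in orange and list medians as lines. Medians run from -0.74 for cytosolic ribosomal proteins to 2.12 for neutrophil markers.

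Hepatocyte identity and zonation genes showed few calls. Of 24 hepatocyte transcription factors 3 were higher, and 4 with p adjusted over the list alone: Prox1 at 1.73 (SE 0.36), Onecut1 at 1.59 (SE 0.31) and Thrb, a thyroid hormone receptor, at 1.36 (SE 0.19). The list median was 0.48 with a camera adjusted p of 0.0637, which was 0.0334 with the mouse as a block, 0.0354 with library totals, 0.0333 with no filter, 0.802 with an estimated correlation, 0.04 without TERT(High) of mouse 1, 0.0318 without TERT(High) of mouse 3, 0.011 without TERT(Low) of mouse 2 and 0.0166 without mouse 2. After the length and GC correction it was 0.0378, and 0.00406 with the mouse as a block. Hnf4a, a master regulator of hepatocytes, was at 500 ± 179 against 370 ± 64.0 CPM (adjusted p = 0.39), and Alb, serum albumin, at 83330 ± 6153 against 62650 ± 12102 CPM (adjusted p = 0.24). Pericentral genes (median -0.35, adjusted p = 0.178), periportal genes (-0.05, 0.734) and midlobular genes (0.09, 0.947) did not pass. The pericentral list passed without TERT(High) of mouse 2, without TERT(Low) of mouse 3 and without mouse 2, at adjusted p of 0.0259, 0.0371 and 0.0417, and after the length and GC correction at 0.034, or 0.0184 with the mouse as a block. Glul, the pericentral glutamine synthetase, was at 99.4 ± 60.7 against 145 ± 71.2 CPM and Cyp2e1 at 3377 ± 530 against 4298 ± 642 CPM (adjusted p of 0.542 and 0.294). Ass1 and Cyp2f2, of the periportal zone, had log2 fold changes of -0.02 (SE 0.53) and -0.04 (SE 0.25). The Wnt targets Axin2 and Lgr5 were near the filter, with log2 fold changes of 0.55 (SE 0.45) and -0.04 (SE 0.45). Sox9, of cholangiocytes and progenitors, was at 0.884 ± 0.0975 against 1.23 ± 0.772 CPM. Genes biased to male (-0.30, 0.45) or female hepatocytes (-0.23, 0.988) did not pass as lists, and Trim24 was the 1 female-biased gene past the threshold (0.98, SE 0.23), but 0 were with p adjusted over the list alone.

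Telomere, cell cycle and growth lists did not pass either. The telomerase complex list had 2 of 10 members lower, over all genes and over the list alone: Nhp2 at -0.80 (SE 0.13) and Nop10 at -0.73 (SE 0.14), small proteins shared with the particles that modify ribosomal RNA (list median 0.13, adjusted p = 0.801). After the length and GC correction Nhp2 and Nop10 were at -0.25 (SE 0.14) and -0.36 (SE 0.21), with edgeR adjusted p of 0.432 and 0.423. Telomere protection genes had a median of 0.41 (adjusted p = 0.495), with Terf2ip at 0.41 (SE 0.16) and Tinf2 at -0.44 (SE 0.21). S phase (-0.03, 0.801) and G2 and M phase genes (0.17, 0.951) included Ect2, a regulator of cytokinesis, as the 1 called member (0.675 ± 0.154 against 0.162 ± 0.0291 CPM, adjusted p = 0.0468, and 0.0541 with the mouse as a block, and not called over the list alone). Mki67, a proliferation marker under the filter, had 38 counts in TERT(High) of mouse 1 and 0 to 5 in the other libraries. Cyclin-dependent kinase inhibitors and G0 genes (0.05, 0.647), with Cdkn1a at 90.5 ± 43.2 against 112 ± 58.1 CPM, and Wnt targets (0.12, 0.737), with Ccnd1 at 118 ± 39.1 against 108 ± 24.9 CPM, did not pass. Insulin and growth hormone signalling genes had 4 of 18 members higher, namely Jak2 at 1.42 (SE 0.31), Insr, the insulin receptor, at 1.23 (SE 0.23), Pik3r1 at 1.12 (SE 0.22) and Irs1 at 1.02 (SE 0.22), and 4 higher and 1 lower with p adjusted over the list alone (median 0.39, adjusted p = 0.298). The adjusted p of Irs1 was 0.0544 with the mouse as a block. Corrected for length and GC, Jak2, Insr, Pik3r1 and Irs1 had log2 fold changes of 1.02, 0.63, 0.55 and 0.54 (edgeR adjusted p of 0.1385, 0.3869, 0.2352 and 0.3745). Circadian clock genes (0.31, 0.298) had Rora at 1.30 (SE 0.26) and YAP and TAZ targets (0.59, 0.178) had Lats2 at 0.80 (SE 0.17) as their 1 higher member each, also over the list alone. With the mouse as a block the adjusted p of Rora and Lats2 were 0.0544 and 0.0525. Their corrected log2 fold changes were 0.40 and 0.61 (edgeR adjusted p of 0.601 and 0.153). Notch pathway (0.66, 0.513), TGF-beta target (0.26, 0.905), interferon response (0.01, 0.951) and NF-kB target genes (0.36, 0.737) did not pass.

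Several metabolic, secretory and RNA lists that did not pass held a few genes past the threshold. Apolipoproteins and lipoprotein assembly factors had Apob and Abca1, the cholesterol exporter at 1.43 (SE 0.30), higher and 3 of 20 members lower, among them Apoc4 and Apoc2, at -1.01 (SE 0.16) and -0.79 (SE 0.18). With the mouse as a block the adjusted p of Apoc2 was 0.0519. Over the list alone 2 were higher and 8 lower, and the list did not pass (median -0.33, adjusted p = 0.298). Complement and acute phase genes included Hc, higher at 1.65, and C8g, lower at -0.93 (SE 0.16), both also over the list alone (0.00, 0.951). Of the coagulation and plasma protein genes F5, coagulation factor V, was higher at 315 ± 91.7 against 73.5 ± 22.3 CPM, and of the bile acid genes Abcb11, the bile salt export pump, at 266 ± 36.6 against 121 ± 19.2 CPM, each also over the list alone (-0.10, 0.796, and 0.02, 0.951). The tricarboxylic acid cycle (-0.14, 0.37, and 0.0274 by fry) had Sdhc and Sdhd lower, at -0.82 and -0.76, and 3 lower over the list alone. Fatty acid oxidation and ketogenesis (-0.23, 0.492) had Etfb lower at -0.79 (SE 0.14), also over the list alone. Translation factors had 2 of 34 members higher, of which Eif3a was at 2.03 (SE 0.29), and 4 lower, such as Eif3i at -0.80 (SE 0.12), with 6 higher and 8 lower over the list alone (-0.09, 0.518). RNA splicing factors were split, with Hnrnpu at 1.83 (SE 0.33) and Sf3b1 at 42.8 ± 4.43 against 21.4 ± 1.88 CPM higher, and Snrpd2 at -0.82 (SE 0.13) and Snrpg at -0.70 (SE 0.14) lower, and 3 higher and 2 lower over the list alone (0.10, 0.833). Actin cytoskeleton and adhesion genes (0.12, 0.881) had Myl6 lower at -0.79 (SE 0.13), also over the list alone, and passed as higher after the length and GC correction (median 0.35, adjusted p = 0.0266, and 0.021 with the mouse as a block). Peroxisome (-0.09, 0.495), glycolysis and gluconeogenesis (-0.22, 0.228), urea cycle and amino acid catabolism (-0.12, 0.495), fatty acid and triglyceride synthesis (0.15, 0.636) and cytochrome P450 genes (-0.15, 0.241) did not pass.

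Heat shock proteins (0.50, 0.45), the unfolded protein response (-0.18, 0.495), NRF2 targets (0.07, 0.971), p53 targets (0.08, 0.919), immediate early genes of tissue dissociation (-0.29, 0.734) and long nuclear-retained RNAs (-0.26, 0.919) did not pass, where the pair of values in brackets is the median log2 fold change and the camera adjusted p throughout. Malat1, an abundant nuclear RNA of the last list, was at 227 ± 56.0 against 102 ± 26.4 CPM (log2 fold change 1.15, SE 0.27, adjusted p = 0.0508, and 0.0407 with the mouse as a block). Beside the hepatocyte transcription factor, pericentral, macrophage and erythroid lists, the lists that did not pass with all libraries and passed with some left out were heat shock (adjusted p = 0.0265 without TERT(High) of mouse 2 and 0.0288 without mouse 2), urea cycle (0.0212 without TERT(High) of mouse 2 and 0.01 without TERT(Low) of mouse 1), immediate early genes (0.0115 without TERT(Low) of mouse 3 and 0.0165 without mouse 3), cytochrome P450 (0.0451 without TERT(Low) of mouse 2 and 0.0273 without mouse 2) and fatty acid synthesis (0.0417 without mouse 2). After the length and GC correction with the mouse as a block the heat shock and macrophage lists passed as higher (adjusted p of 0.014 and 0.00638). The 30 lists with 0 members past the threshold by edgeR held 518 genes, of which 46 were higher and 43 lower at an unadjusted p under 0.05. DESeq2 called 25 higher and 25 lower among them, and limma-voom 12 higher and 16 lower. With the mouse as a block edgeR called 6 higher and 10 lower, and DESeq2 44 higher and 66 lower. Median and camera direction differed in sign for the telomerase complex, midlobular, female-biased, erythroid and G2 and M phase lists, and the mean differed in sign from the median for translation factors, NRF2 targets, cholangiocyte markers and S phase genes.

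The authors' deposited table of results holds 10851 genes of the count table. At an adjusted p under 0.05 it has 1712 genes higher and 1460 lower in TERT(High) cells. Its log2 fold changes had a Spearman correlation of 0.984 across 10836 genes with those of edgeR, with the same sign for 97.1%. Of the edgeR calls listed there, 583 of 584 higher and 489 of 493 lower genes were past the threshold in the same direction, and 0 in the opposite one. For Apob the authors' deposited table gives a log2 fold change of 2.67 and an adjusted p of 8.06e-45.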

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

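Beside the 588 genes higher and 493 lower, the strict filter gave 888 and 615, DESeq2 1527 and 1266, and limma-voom 1358 and 1103. Library totals as scaling left 19 lower genes. With the replicate block edgeR gave 721 and 571 and DESeq2 1628 and 1446, and of the 93 named genes past the threshold 9 lost their call with it: Golga3, Nolc1, Flt4, Ect2, Lats2, Irs1, Rora, Apoc2 and Atp5g1 (adjusted p of Atp5g1 0.0519). Scd1, Id3 and Malat1 gained one (0.0482, 0.0446 and 0.0407), and among lists the block changed the call of cholesterol synthesis, neutrophil markers and hepatocyte transcription factors, and of no other named gene or list. A test against a 1.5-fold change gave 0 and 0 genes (1163 higher and 290 lower at an unadjusted p under 0.05), as did an adjusted p under 0.01 (2164 and 1649) and the length and GC correction (1636 and 675). The correction gave 113 lower genes with the replicate block and 317 with DESeq2. With libraries or mice left out the counts ran from 0 to 1662 higher and from 0 to 1584 lower, where the 0 came from edgeR without any 1 library except TERT(High) of mouse 1 and the highest from DESeq2 without that library. Lists higher were 4, against 2 with limma-voom, 0 with an estimated correlation, 0 with fry, 8 with the correction and the replicate block, and 3 to 7 with libraries left out. Lists lower were 9, against 0 with an estimated correlation. Eif4g2 reversed under the correction, to -0.0423, -0.0353 with the replicate block and -0.0422 with DESeq2. Hba-a1, not past the threshold in all libraries, reversed to -2.22 without TERT(High) of mouse 1 (-2.22 with DESeq2), where that library held 3959 of its counts, and ran from -2.29 without mouse 1 to 1.99 without mouse 2. The cholesterol synthesis median ran from -0.61 without mouse 3 to 0.0249 without mouse 2. The cause was not tested, except that the threshold alone makes the adjusted p setting stricter. Of the 93 named genes past the threshold, 92 kept their call with DESeq2 and 48 with library totals. The fit without mitochondrially encoded genes gave no value because the count table holds none. Upper quartiles gave 542 and 712, no filter 492 and 336, DESeq2 size factors 529 and 464, thinning to the shallowest library 573 and 482, and edgeR without robust dispersion 620 and 515. Named genes that lost their call were Hspa9, Eif4g2, Gstt2, Trim24 and Ect2 with DESeq2 size factors, Hspa9, Eif4g2, Gstt2, Jak2 and Lats2 with upper quartiles, and with no filter 13, namely Hspa9, Eif4g2, Gstt2, Trim24, Ect2, Cyb5a, Apoa2, Apoc2, Lyve1, Flt4, Hspg2, Atp5g1 and Atp5g2.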

Other observations

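Families of genes with shared names were compared after the results were seen, and 23 of 81 passed camera at an adjusted p under 0.05, while 0 passed with an estimated correlation (lowest 0.49). Ubiquitin-specific proteases (Usp) had 15 of 43 members higher in TERT(High) cells (median log2 fold change 0.69, camera adjusted p = 9.62e-08) and zinc finger proteins (Zfp) 13 of 321 (median 0.59, camera adjusted p = 4.65e-06). The Zfp calls are a smaller share than the 588 higher among all 13288 tested genes, so that family stands out by its median only. Centrosomal (Cep), collagen (Col), myosin (Myo) and RNA helicase genes (Dhx, Ddx) had medians of 0.86, 1.13, 1.24, 0.68 and 0.44, and 2 of the collagens, Col1a1 and Col1a2, were abundant in a single library. Transmembrane proteins of the Tmem series had 14 of 176 lower and 1 higher (median -0.38, camera adjusted p = 3.54e-05). After the length and GC correction the medians of Usp, Zfp and Tmem were 0.33, 0.38 and -0.15.

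Some genes set single libraries or mice apart. Col1a1 and Col1a2, fibroblast collagens, had 7758 and 6447 counts in TERT(High) of mouse 1 and 6 to 314 and 13 to 220 in the others, and Fos, an immediate early gene, had 504 and 120 counts in mouse 3 against 2568 to 5134 in mice 1 and 2. Xist, expressed from the inactive X chromosome of females, had 37 counts in TERT(High) of mouse 1 and 2 to 6 in the others, and the labels do not give the sex of the mice. On the Y chromosome, Uty (335, 284 and 273 counts in TERT(High), 142, 126 and 139 in TERT(Low) cells) and Ddx3y (1655, 515 and 1085, against 236, 197 and 349) had more counts in TERT(High) cells of all 3 mice, with adjusted p of 0.0332 and 0.0525 by edgeR. Counts of Uty and Ddx3y in every library, beside 2 to 37 of Xist, argue against a female among the 3 mice.

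All tests below were chosen after the results were seen. The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split called 588 genes higher and 493 lower, and the highest other split 671 in 1 direction, so 2 of 10 splits reached each real count. That other split (TERT(High) 1 and 2 with TERT(Low) 2) follows the first principal component, which held 55.3% of variance, while the 3 other splits that part all 3 pairs gave 0 genes. For lists, 9 of 10 splits gave at least the real 13 (highest other 25), and splits parting all pairs gave 14, 18 and 14.

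A trend of counts with transcript length in each library could explain part of the gene changes. Higher genes picked in 2 mice kept 124.51%, 61.81% and 64.55% of their change in held-out mice 1, 2 and 3 after the correction. In mouse 1 the correction thus enlarged the difference. Lower genes kept 47.03%, 32.14% and 22.12%. For the higher genes the values argue against the trend with annotated length, as removed here, as the whole cause. A trend with the true length of the expressed transcripts could remain, and the lower genes leave the trend open. Against lists matched for transcript length, the percentiles of the medians were 0.02 for cytosolic ribosomal proteins (median -0.74, matched lists -0.62), 1.49 for mitochondrial ribosomal proteins (-0.49, matched -0.38) and 0.29 for cholesterol synthesis. They were 100 each for chromatin regulators (1.36, matched 0.79, or 1.02 by coding length), endothelial and neutrophil markers. Most of both ribosomal decreases and of the chromatin increase is also seen in matched lists. Matched genes were drawn independently, while members of a list can move together (estimated correlation 0.06 to 0.628 for these lists). Extreme percentiles thus cannot decide whether length was the whole cause. The erythroid list also reached 100, but had a median of -2.14 without TERT(High) of mouse 1. The percentiles were 16.86 for complexes II to IV, 18.67 for the ATP synthase, 85.61 for the proteasome, 44.37 for conjugation and 93.98 for major urinary proteins, which length alone could give. The 2 kinds of matching parted for complex I (4.36 by transcript and 0.3 by coding length) and ribosome biogenesis (99.9 and 88.74), which leaves both open. RNA quality and a biological difference in long transcripts were not separated, since no RNA integrity values were used here.

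RNA of sinusoidal endothelial cells in the sorted TERT(High) cells could raise endothelial markers. Of the 10 most abundant markers 8 were higher in all 3 mice, where 28.2% of all genes were, but 4 of the 10, Clec4g (-0.08), Gata4 (0.10), Fcgr2b (0.28) and Eng (0.42), lay below the median of 1.14 by over 2 SE. These 4 have the shortest transcripts of the 10 (1242 to 3544 nt, the others 4747 to 8228 nt), and after the length and GC correction their log2 fold changes were 0.42, 0.22, 0.13 and 0.44, still below the 0.69 to 1.83 of the other 6. The question stays open, and expression of these genes by hepatocytes was not tested.

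For 329 genes the mean normalized count differed over 1.5-fold between the count table and the authors' deposited results. Of these 69.51% overlap another gene or belong to a gene family, against 50.22% of the rest (Fisher's exact test across genes, p = 4.5e-12), so shared reads may account for part of them, which stays open.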
